A study of Mus musculus with 6 samples.

How the data were processed

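Total RNA from 6 snap-frozen mouse livers was sequenced on a DNB platform, 3 livers from mice injected with AAV8 carrying a scrambled shRNA and 3 from mice injected with AAV8 carrying an shRNA against S1pr2. The mice were 7 to 12 weeks old. According to the series text they were male and received dexamethasone at about 0.84 mg/kg for 7 days in the drinking water; the sample labels name the shRNA only. Each library came as a table with 1 line per gene, identified by Entrez gene ID and symbol. Per the submitters' processing notes, HISAT2, Bowtie2, RSEM 1.2.12 and DESeq2 were used with the mm9 mouse build; the role and order of these tools, the read filters, the strand handling and the shRNA sequence are not given in the sources used here. The deposited tables hold for each gene an expected count, which is the number of fragments RSEM assigns to the gene without scaling to depth. They also hold FPKM, which the authors scaled per kilobase of transcript and to the number of mapped fragments and gave to 2 decimals, with 0.01 as the lowest value listed. Between 24.5 and 25.2% of the listed genes had an expected count that was not a whole number, as happens when a read is shared between genes. Transcripts overlapping on opposite strands cannot be separated without the strand handling. No genome coordinates are reported, because the submitters used mm9 and the annotation used here for 3' UTRs was GENCODE M21 on GRCm38.

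The totals of expected counts were 16870737, 17410160 and 17279103 in scramble livers 1 to 3 and 17145580, 16558775 and 16646555 in knockdown livers 1 to 3. The libraries listed 14522, 14755, 14976, 15106, 14760 and 14803 genes in the same order. Of 16426 genes listed in at least 1 library, 13402 were listed in all 6. The other 3024 were treated as having 0 counts where they were not listed, and the median of their highest count was 2. Between 19 and 23 genes per library had no symbol and carried 0.204 to 0.255% of the counts; they were kept under their gene ID. The 10 most abundant genes took 25.2, 27.0 and 27.5% of the counts in the scramble and 22.2, 24.6 and 24.2% in the knockdown livers. All 15 pairs of libraries differed, by a chi-square per degree of freedom of 20.1 to 193.5 over genes with at least 20 counts, so no library was a copy of another.

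Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr of edgeR 4.0.16 at its defaults (minimum count 10), which left 12230 genes, and normalised by the trimmed mean of M-values (TMM), with factors of 0.968, 0.924, 0.957, 1.154, 0.987 and 1.027. The groups were compared with the edgeR quasi-likelihood F test, two-sided, with robust dispersion estimation and group as the only factor, in R 4.3.3. The common biological coefficient of variation was 20%. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors belong to the log2 fold changes of that fit; log2 CPM values used a prior count of 2.

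The design, the settings, the alternatives, the rule for naming genes and 38 gene lists (786 symbols, of which 774 were found in the tables) were fixed before the data were examined. They covered sugar, lipid, bile acid, sphingolipid and S1P genes, glucocorticoid targets, clock and sex-biased genes, stress and interferon responses, hepatic zonation and markers of hepatocytes and of other cell types. A list was tested when at least 4 members were tested, which held for 35 lists. The test was camera of limma 3.58.1 with the inter-gene correlation preset at 0.01, on edgeR log2 CPM of the tested genes, with Benjamini-Hochberg adjustment over the lists; it was repeated with the correlation estimated from the data and with the self-contained directional test fry. The number of genes past the test was counted over all genes tested and adjusted over the list alone. Named genes were the S1P receptors, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM in the higher group, no overlap between groups and a symbol that is not a predicted or clone name, and up to 4 members with the smallest p of each list that passed and of the sugar, lipid, bile acid, glycogen, glucocorticoid and interferon lists. A few genes that meet this rule are not reported here. An exact two-sided permutation test over all 20 assignments of the livers was run for the S1pr2 CPM.

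The alternatives were DESeq2 size factors and upper-quartile factors in place of TMM, no filter or a mean of at least 1 CPM in place of filterByExpr, the DESeq2 1.42.0 Wald test and limma-voom in place of edgeR, dispersion estimation without the robust option, the replicate number as a block, limma on log2 FPKM with a pseudocount of 0.1 or 1 for genes with a mean FPKM of at least 0.1, a minimum fold change of 1.5, and each liver left out in turn. Genes without a certain pair of 7-mers in the 3' UTR were added as an alternative after the data were seen.

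For the closing section, every 7-mer (16384 in all) was scored as present or absent in the annotated 3' UTRs of at least 50 bases of 11992 tested genes. The signed gene statistic was regressed on each. Covariates were the log length and the GC content of the UTR, their squares and their product. The other 238 tested genes had no such UTR and were left out. Bootstrap intervals used 10000 draws over genes. Gene Ontology terms named in the deposited tables with at least 10 tested genes were tested with Fisher's exact test, with the tested genes that carry a term as background (4622 tests). Reading of the tables, the 7-mer scan and the figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

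The tests were tested on simulated data, with counts drawn at the depth, gene means and dispersions of the libraries and planted changes of 1.5, 2 and 4-fold. The edgeR test recovered 20.9, 62.7 and 92.4% of these genes, DESeq2 28.4, 74.6 and 93.9% and limma-voom 19.4, 65.7 and 92.4%, with 0 in the wrong direction. In numbers these were 14, 42 and 61 genes in edgeR, 19, 50 and 62 in DESeq2 and 13, 44 and 61 in limma-voom. The tests also called 18, 50 and 18 unchanged genes in the same order. In each test these were a larger share of the calls than the adjusted p threshold is meant to allow. Calls in the livers may likewise hold more false ones than that threshold states. The list test called the 1 shifted list of 35, also with an estimated correlation. Genes were drawn independently of each other, so this says nothing about lists whose genes vary together. In the 7-mer scan, permuted statistics gave a largest absolute z of 4.11, and a 7-mer planted in 177 genes reached z of -2.05, -4.45 and -9.24 at shifts of 0.3, 0.6 and 1.2, against a Bonferroni bound of 4.67.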

Results

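RNA was sequenced from 6 mouse livers on a mixed B6:sv129 background. Of these, 3 came from mice given an AAV8 vector carrying a scrambled short hairpin RNA (shRNA) and 3 from mice given AAV8 carrying an shRNA against S1pr2, a G protein-coupled receptor for the lipid sphingosine-1-phosphate (S1P). The series describes male mice that drank dexamethasone, a synthetic glucocorticoid, for 7 days. No single library carries a label for that treatment, and no untreated group was analysed here. The libraries held between 16558775 and 17410160 expected counts and listed 14522 to 15106 genes each. Nothing in the labels says that the replicates came from separate animals, so the p-values measure only the spread between these samples.

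The comparison of S1pr2 shRNA with scramble livers covers effects of the lower S1pr2 transcript together with any other effect of the hairpin. The target itself was lower in every knockdown liver. S1pr2 (Entrez gene 14739) fell by 1.12 on the log2 scale (SE 0.24, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0301). Its level went from 5.43 ± 1.14 normalised read counts (CPM, read counts scaled to library size; mean ± SD, n = 3) to 2.49 ± 0.474 (n = 3). Its level was 4.41, 5.23 and 6.66 CPM in scramble livers 1 to 3 and 3.04, 2.20 and 2.22 CPM in knockdown livers 1 to 3. In the knockdown livers 46% of the transcript remained. These levels rested on 72, 84 and 110 counts in the scramble and 60, 36 and 38 counts in the knockdown livers. In the deposited FPKM the group means were 1.82 ± 0.38 and 0.93 ± 0.26 (SD, n = 3 each). S1pr1 (13609), the S1P receptor abundant in endothelial cells, rose by 0.68 log2 units (SE 0.13, edgeR adjusted p = 0.0210), from 36.8 ± 5.14 to 58.9 ± 4.89 CPM (n = 3 each). S1pr3 (13610) had a log2 fold change of 0.41 (SE 0.43, edgeR adjusted p = 0.619) and S1pr5 (94226) of 0.21 (SE 0.40, edgeR adjusted p = 0.796). Neither passed the test, and S1pr4 was below the count filter. As a list, the 4 tested receptors had 1 member that rose and 1 that fell, also when adjusted over the list alone, with a median of 0.31 and a list adjusted p of 0.903. Of the 9 tested genes of S1P metabolism and transport, 0 passed, also adjusted over the list alone. Their median was 0.00, their mean 0.04 and the direction of the list test lower (adjusted p = 0.927). An exact two-sided permutation test of the S1pr2 CPM over the 20 assignments gave p = 0.1, the smallest that 3 against 3 allow. The S1pr2 call was lost when scramble liver 2 (adjusted p = 0.0785), scramble liver 3 (0.0962), knockdown liver 2 (0.117) or knockdown liver 3 (0.101) was left out. It was also lost on FPKM with a pseudocount of 0.1 (log2 fold change -0.90, adjusted p = 0.0661) or 1 (-0.54, adjusted p = 0.0677). Over all alternatives its edgeR, DESeq2 or limma adjusted p ran from 0.00483 to 0.117.

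**Figure D1:**
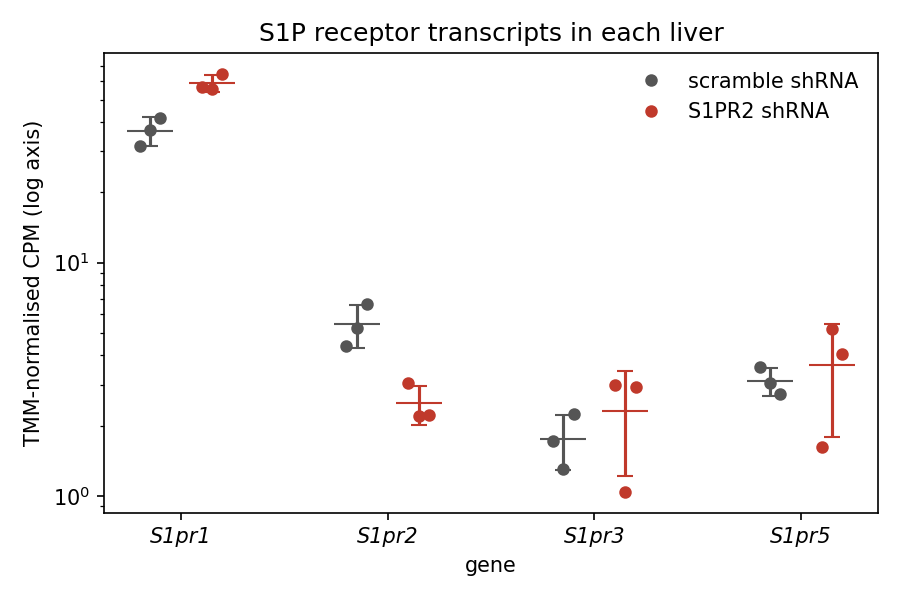
TMM-normalised read counts (CPM, log axis) of the 4 tested S1P receptor genes in scramble (grey) and S1pr2 shRNA (red) livers, with 1 point per liver, a line at the mean and bars for the SD of the 3 livers of each group. S1pr2 was lower in all 3 knockdown livers (2.20 to 3.04 CPM) than in the scramble livers (4.41 to 6.66 CPM), and S1pr1 was higher.

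Across the transcriptome, 937 of 12230 tested genes changed: 369 rose and 568 fell in the knockdown livers. Mttp, which loads triglyceride onto nascent lipoproteins, fell. It was 5.54-fold lower, from 790.3 ± 110.5 to 142.8 ± 13.6 CPM (SD, n = 3 each; log2 fold change -2.47, SE 0.16, edgeR adjusted p = 0.00153). Cytochrome P450 genes were among both the rises and the falls. Cyp2c23, which makes epoxides from arachidonic acid, rose from 42.6 ± 19.0 to 422 ± 24.8 CPM (log2 fold change 3.31, SE 0.32; n = 3 each). Cyp2b10, a xenobiotic-inducible enzyme, fell from 1759 ± 662 to 222 ± 124 CPM (-2.98, SE 0.57; n = 3 each). Genes changed by at least 2-fold numbered 125 among the rises and 161 among the falls, and the median absolute log2 fold change of the called genes was 0.78. The other large falls were in A4gnt (-3.43) and St6galnac4 (-2.73), both glycosyltransferase genes. Next to them were Xlr3a (-3.55), Plcl1 (-3.34), Hcn3 (-2.84), a cation channel gene, the clock gene Ciart (-2.64), Cyp2b23 (-2.97) and Cyp2b19 (-2.68). The other large rises were in Cdh1 (2.68; 7.01 to 44.9 CPM), which encodes E-cadherin, and Igfbp2 (2.63; 31.0 to 192 CPM), a binding protein for insulin-like growth factors. They were followed by Rnf186 (2.73), Cd4 (2.94; 0.845 to 6.52 CPM), Pdilt (2.53), Acsm2 (2.41), Apol9a (3.17) and Tmem254b (4.11). Cib3 had 1 count over the 3 scramble livers and 311 over the knockdown livers, a ratio of 286 with a 95% exact counting interval of 51 to 11300, which covers counting error only. Tmem254b, Apol9a, Acsm2, Plcl1, Cyp2b10, Cyp2b19 and Cyp2b23 had fractional read counts in 5 or 6 libraries, and Xlr3a in 1. Part of their reads was shared with related sequences, so their values are uncertain. The paralog Tmem254c, looked at after its values were seen, had a log2 fold change of -1.27 (edgeR adjusted p = 0.582).

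The first principal component, 45.1% of the variance of log2 CPM, placed scramble livers 1 to 3 at -46.3, -18.5 and -18.1 and knockdown livers 1 to 3 at 36.3, 25.4 and 21.2. In 3906 genes (31.9%) every liver of one group lay above every liver of the other, against the 10% that chance gives. The split between rises and falls depended on the processing. With TMM factors 60.6% of the calls were lower, with DESeq2 size factors 60.7% and with upper-quartile factors 48.5% of 982 calls. On FPKM, where the test and the gene filter differed as well, the shares were 30.4% of 873 calls (pseudocount 0.1) and 30.6% of 819 calls (pseudocount 1). There the median of all genes stood at 0.152 and 0.109 log2 units, against 0.012 with TMM factors, and no called gene changed sign. The number of changed genes was 533, 456 and 400 without scramble liver 1, 2 or 3, 643 and 414 without knockdown liver 1 or 3, and 231 without knockdown liver 2. Of the 74 named genes that passed, 20 passed with any single liver left out and under every other setting except the replicate block. Among them were G6pc, Gpi1, Me1, Thrsp, Acaca, Acacb, Mttp, Acot1, Abcc3, Gstt3, Susd4, Cyp4a12b, Iigp1, Cyp2b19, Cyp2b23, Cib3, Rnf186, Cyp2c23 and Pdilt. The other 54 named calls were lost without at least 1 liver or under another setting, most often without knockdown liver 2 (46 named genes). The counts were 38, 30, 28, 25 and 19 without scramble liver 3, scramble liver 2, knockdown liver 3, scramble liver 1 and knockdown liver 1. Klb, Hcn3, Lgr5 and Cdh5 lost their call whichever liver was left out. With other filters, tests or scalings, S1pr2, Crp, Orm3, Klb, Krt23, Ciart, Cyp2b9, Cyp2b10, Hcn3, Acsm2, Apol9a, Cd4, Tmem254b, Ahr and Cd36 lost theirs.

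Genes of sugar and lipid synthesis were lower together in the knockdown livers. Of the sugar and lipid lists, however, only glycolysis and fructose use also passed the fry test (adjusted p = 0.0255). G6pc, the catalytic subunit that releases glucose from glucose-6-phosphate, fell from 987 ± 313 to 311 ± 31.2 CPM (n = 3 each; log2 fold change -1.66, SE 0.23, edgeR adjusted p = 0.00887), and Slc37a4, the transporter that feeds it, fell by 0.88 (SE 0.17, edgeR adjusted p = 0.0221). In fructose use and glycolysis, Khk (-1.21, SE 0.21), which phosphorylates fructose, Tkfc (-1.13, SE 0.20) and Gpi1 (-1.30, SE 0.16) fell. Of the lipogenic genes, Thrsp fell from 1238 ± 366 to 309 ± 25.2 CPM (-2.00, SE 0.24) and Me1, a source of NADPH, from 505 ± 72.9 to 136 ± 35.8 CPM (-1.89, SE 0.22). The acetyl-CoA carboxylases Acaca (-1.48, SE 0.23) and Acacb (-1.43, SE 0.18) fell as well. Of the cholesterol synthesis enzymes, Dhcr7 (-0.88, SE 0.15) and Hsd17b7 (-0.98, SE 0.20) fell. Gpi1 and Tkfc had fractional counts in 6 libraries and Hsd17b7 in 1, so these are uncertain.

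Of 16 fatty acid synthesis genes, 0 rose, 6 fell and 10 did not pass (0 and 11 adjusted over the list alone). Their median log2 fold change was -1.40 (adjusted p = 1.6e-06; adjusted p = 0.565 with an estimated correlation). Of 24 cholesterol synthesis and uptake genes, 0 rose, 3 fell and 21 did not pass (0 and 10 adjusted over the list alone). The median of these genes was -0.66 (adjusted p = 1.69e-06; adjusted p = 0.585 with an estimated correlation). Stard4 stood at -0.83 (edgeR adjusted p = 0.0661). In the glycolysis and fructose list, 6 of 18 genes fell, 0 rose and 12 did not pass (8 and 0 adjusted over the list alone). Here the median was -0.45 (adjusted p = 3.35e-06; adjusted p = 0.362 with an estimated correlation). Of 18 gluconeogenesis genes, 2 fell, 0 rose and 16 did not pass (5 and 0 adjusted over the list alone). Their median was -0.49 (adjusted p = 0.00109; adjusted p = 0.585 with an estimated correlation). Fbp1 (-1.45, edgeR adjusted p = 0.0543) and Pcx (-0.68, edgeR adjusted p = 0.0592) did not pass. Without scramble liver 1 the gluconeogenesis median was -0.30 (adjusted p = 0.00959). Among 22 genes of triglyceride synthesis and lipid droplets, 3 fell, 1 rose and 18 did not pass (9 and 1 adjusted over the list alone). The list median was -0.52 (adjusted p = 0.00109; adjusted p = 0.585 with an estimated correlation). Its members included Mttp, the fatty acid transporter Cd36 (-2.18, SE 0.43; 206 to 45.4 CPM), Dgat2 (-0.78, SE 0.16), which adds the last acyl chain of triglyceride, and Fitm1, a lipid droplet protein gene, which rose by 1.14 (SE 0.18).

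**Figure D2:**
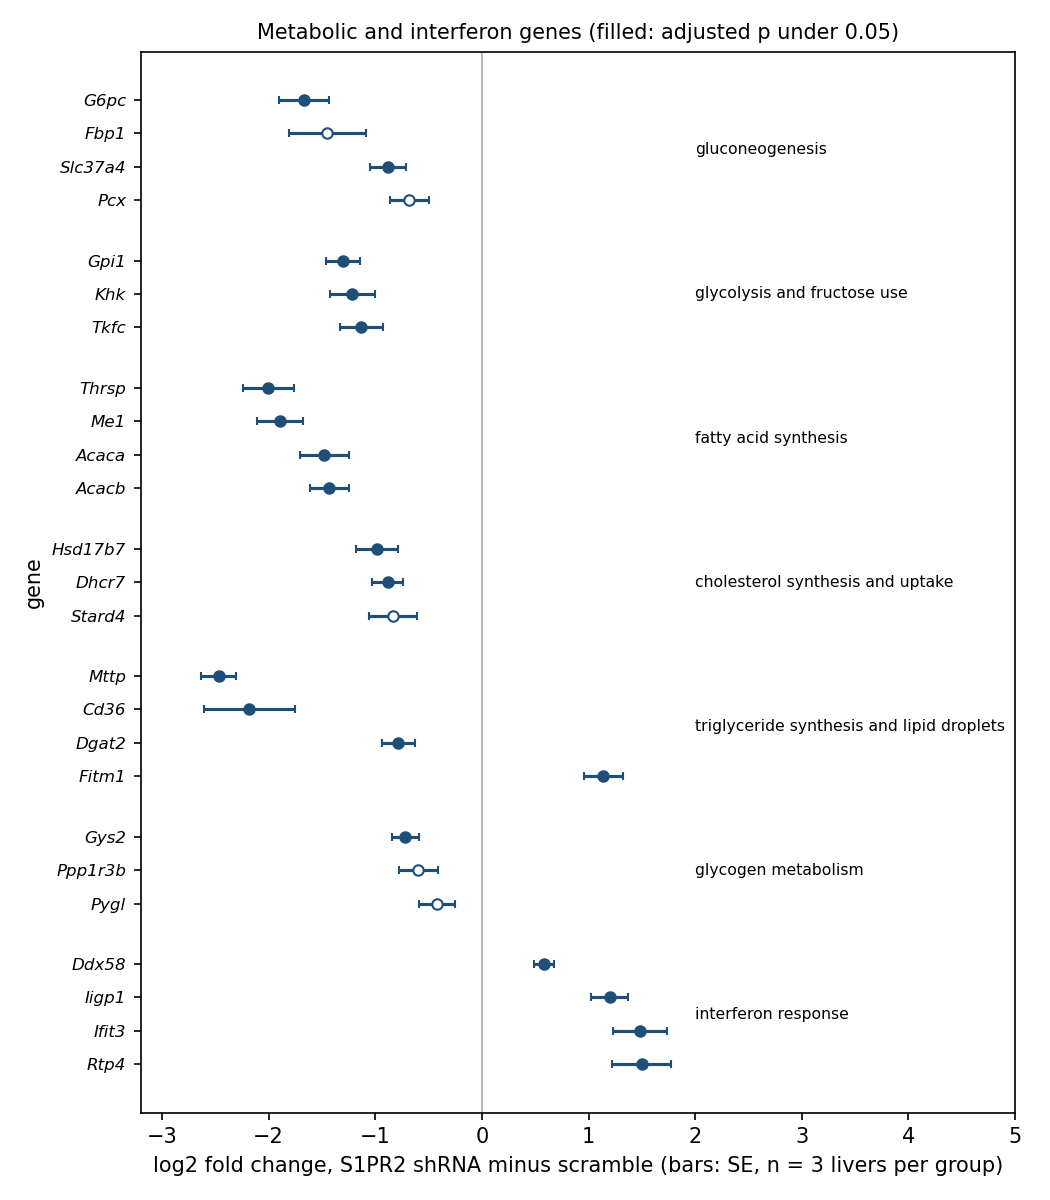
Log2 fold change (knockdown minus scramble) of named genes of the sugar, lipid, glycogen and interferon lists, with points for the edgeR estimate, bars for its SE (3 livers per group) and filled points for genes past the test. The fatty acid synthesis genes lay between -2.00 and -1.43 on this scale, Fitm1 was the metabolic gene above 0 among those plotted, and the interferon genes all lay above 0.

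Fatty acid oxidation, glycogen and bile acid genes did not pass as lists. Of 29 fatty acid oxidation and ketogenesis genes, 1 rose, 0 fell and 28 did not pass, also adjusted over the list alone (median -0.10, adjusted p = 0.258). The riser was Acot1, an acyl-CoA thioesterase (1.15, SE 0.15, edgeR adjusted p = 0.00633), and Slc25a20 (-0.58), Acadvl (-0.47) and Crat (-0.81) did not pass. Of 13 glycogen genes, 1 fell and 12 did not pass, also adjusted over the list alone (median -0.09, adjusted p = 0.264). The faller was Gys2, the liver glycogen synthase (-0.72, SE 0.13, edgeR adjusted p = 0.0178), and Ppp1r3b (-0.59) and Pygl (-0.42) did not pass. Acot1 and Pygl had fractional counts in 6 libraries, Ppp1r3b in 5 and Crat in 1. Of 27 bile acid genes, 3 rose, 1 fell and 23 did not pass (5 and 2 adjusted over the list alone; median 0.08, adjusted p = 0.432). The risers were Abcc3, a basolateral bile acid exporter (2.00, SE 0.22; 65.3 to 262 CPM), and the sterol exporter pair Abcg5 (0.90, SE 0.14) and Abcg8 (0.79, SE 0.19), and the faller was Klb, the FGF co-receptor (-0.40, SE 0.10).

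Glucocorticoid-regulated genes were lower in the knockdown livers, although few passed singly. Dusp1, a phosphatase gene induced by glucocorticoids, fell from 89.3 to 22.1 CPM (log2 fold change -2.01, SE 0.28, edgeR adjusted p = 0.0118), and Sult1e1, the estrogen sulfotransferase, from 674 to 189 CPM (-1.84, SE 0.30). Of the 24 genes, 2 fell, 0 rose and 22 did not pass (2 and 0 adjusted over the list alone), with 21 values below 0. The glucocorticoid list's median was -1.06 (adjusted p = 0.00072; adjusted p = 0.599 with an estimated correlation). Fkbp5 (-2.22, SE 0.58, edgeR adjusted p = 0.0800) and Errfi1 (-1.19, SE 0.34, edgeR adjusted p = 0.0844) did not pass. Mean list values relative to the scramble mean were 0.73, -0.60 and -0.13 in scramble livers 1 to 3 and -0.64, -0.81 and -1.37 in knockdown livers 1 to 3. Without scramble liver 1 the median was -0.47 (adjusted p = 0.0113).

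The female-biased list passed the list test in the lower and the male-biased list in the higher direction, with few of their genes past the test. In the female-biased list Gstt3, a glutathione transferase gene, fell from 188 to 42.7 CPM (log2 fold change -2.14, SE 0.27, edgeR adjusted p = 0.00808), as did Sult1e1, Cyp2b13 (-2.43) and Cyp2b9 (-2.42). Of its 15 tested genes 4 fell, 0 rose and 11 did not pass (6 and 0 adjusted over the list alone). Their median log2 fold change was -1.55 (adjusted p = 0.00147; adjusted p = 0.589 with an estimated correlation). In the male-biased list Susd4 (1.58, SE 0.22) and Cyp4a12b (1.79, SE 0.26; 149 to 513 CPM) rose. In all, 2 of 19 genes rose, 0 fell and 17 did not pass (3 rose and 1 fell adjusted over the list alone). The median of these genes was 0.76 (adjusted p = 0.00389; adjusted p = 0.794 with an estimated correlation). Cyp2d9 (-0.65) and Cspg5 (2.01) did not pass. The control livers were spread widely in both lists, at -1.13, 1.02 and 0.11 for male-biased and 0.93, -1.02 and 0.10 for female-biased genes in scramble livers 1 to 3, and the groups overlapped. Without scramble liver 1 the male-biased median was 0.46 (adjusted p = 0.0408) and the female-biased median -1.14 (adjusted p = 0.00753). Without scramble liver 2 the male-biased median was 1.25 (adjusted p = 2.35e-06). Cyp2b13, Cyp2b9, Cyp4a12b and Cyp2d9 had fractional counts in all 6 libraries and are uncertain. The growth hormone axis list had 0 of 12 genes past the test, also adjusted over the list alone, with a median of -0.02, a mean of 0.12 and a test direction upward (adjusted p = 0.650).

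Circadian clock genes were lower as a list in the knockdown livers. Hlf (log2 fold change -1.36, SE 0.20) and Tef (-1.06, SE 0.22), PAR bZIP transcription factor genes driven by the clock, fell, as did Ciart (-2.64, SE 0.47), a transcriptional repressor gene. Of 21 clock genes 4 fell, 0 rose and 17 did not pass, whereas adjusted over the list alone 8 fell and 2 rose. The clock list had a median of -0.42 (adjusted p = 0.00242; adjusted p = 0.475 with an estimated correlation). The core activator genes Npas2 (0.80, edgeR adjusted p = 0.110) and Arntl (0.77, edgeR adjusted p = 0.130), the pair that rose on the list alone, and Dbp (-0.21) were named after their values were seen.

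Interferon-stimulated genes were higher in the knockdown livers. Iigp1, an interferon-inducible GTPase gene, rose 2.29-fold, from 162 to 371 CPM (edgeR adjusted p = 0.00954). Rtp4 rose from 2.70 to 7.63 CPM (edgeR adjusted p = 0.0205), Ifit3 by 1.48 (SE 0.25) and Ddx58, which encodes the RNA sensor RIG-I, by 0.58 (SE 0.10). Of 34 tested genes 11 rose, 0 fell and 23 did not pass (24 and 0 adjusted over the list alone), and 33 values lay above 0. The interferon list's median was 1.01 (adjusted p = 1.35e-12; adjusted p = 0.362 with an estimated correlation). Iigp1, Ifit3 and Ddx58 had fractional counts in 5 or 6 libraries. Relative to the scramble mean the list stood at 1.55, 1.00 and 0.76 in knockdown livers 1 to 3, against -0.16, 0.13 and 0.03 in the scramble livers. On the same scale the macrophage markers stood at 1.21, 0.12 and 0.22 in the knockdown and -0.53, -0.26 and 0.79 in the scramble livers.

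Among the other cell types of the liver, endothelial markers were higher as a list. Tie1 (log2 fold change 0.73, SE 0.14), Kdr (0.57, SE 0.11), the VEGF receptor gene, Cdh5 (0.49, SE 0.10), which encodes VE-cadherin, and Fcgr2b (0.81, SE 0.17; fractional counts in 6 libraries) rose. Of 22 sinusoidal and vascular endothelial markers 6 rose, 0 fell and 16 did not pass (7 and 0 adjusted over the list alone). Values lay above 0 in 19 and below 0 in 3, the lowest being Lyve1 (-0.83, not passing), named after its value was seen. Here the median was 0.29 (adjusted p = 0.000203; adjusted p = 0.295 with an estimated correlation). Of 13 cholangiocyte markers 4 rose, 0 fell and 9 did not pass (6 and 0 adjusted over the list alone). Their median was 0.50 (adjusted p = 0.0188; adjusted p = 0.585 with an estimated correlation). The risers included the keratin genes Krt18 (1.40, SE 0.24; 105 to 276 CPM) and Krt23 (2.72, SE 0.53) and Anxa4 (0.60, SE 0.11), of which hepatocytes also express some. Kupffer cell and macrophage markers rose as a list (median 0.50, adjusted p = 0.0179; adjusted p = 0.840 with an estimated correlation), while 0 of 21 passed singly, also adjusted over the list alone. Cd5l stood at 0.91, Aif1 at 1.00, Clec4f at 0.67 and Folr2 at 0.78. The macrophage list stood at 1.21, 0.12 and 0.22 in knockdown livers 1 to 3 and at -0.53, -0.26 and 0.79 in the scramble livers. Its call was lost without knockdown liver 1 (median 0.10, adjusted p = 0.349), scramble liver 1 (0.40, adjusted p = 0.101) or scramble liver 2 (0.39, adjusted p = 0.0694). Without scramble liver 3 the macrophage median was 1.07 (adjusted p = 2.47e-05). The call was lost as well with upper-quartile factors (0.56, adjusted p = 0.0592) and on FPKM with a pseudocount of 0.1 (0.71, adjusted p = 0.135) or 1 (0.52, adjusted p = 0.123). The cholangiocyte call was lost without scramble liver 1 (0.43, adjusted p = 0.115) and on FPKM with a pseudocount of 0.1 (0.62, adjusted p = 0.0823) or 1 (0.34, adjusted p = 0.0918).

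Of 24 stellate cell and fibroblast markers 0 passed, also adjusted over the list alone (median 0.34, adjusted p = 0.178). Of 16 hepatocyte markers 2 fell, among them Apoc3 (-0.96), named after its value was seen, and 14 did not pass, also adjusted over the list alone (median -0.23, adjusted p = 0.0663). Albumin took 9.99, 10.02 and 12.34% of the counts in scramble livers 1 to 3 and 6.55, 8.29 and 8.78% in knockdown livers 1 to 3, with a log2 fold change of Alb of -0.59 (edgeR adjusted p = 0.198). Of 5 neutrophil and 9 erythroid markers 0 passed, also adjusted over the list alone. The medians were -0.06 and -0.05, the mean of the neutrophil list was 0.02 with a test direction upward, and the adjusted p were 0.772 and 0.903. The lists for T, B and NK cells (25 genes, 2 tested), pancreatic acinar cells (19 genes, 2 tested) and adipocytes and muscle (15 genes, 3 tested) had too few tested members for a list test.

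Pericentral hepatocyte genes, those expressed around the central vein, rose as a list. Cyp1a2 rose from 294 to 957 CPM (log2 fold change 1.70, SE 0.28), and its regulator Ahr (1.51, SE 0.32), Lgr5 (0.88, SE 0.18) and Rnf43 (0.53, SE 0.09), both Wnt pathway genes, rose as well. Of 19 tested genes 4 rose, 0 fell and 15 did not pass (6 rose and 1 fell adjusted over the list alone). Values lay above 0 in 14 and below 0 in 5. Glul (-0.002), Cyp2e1 (0.24) and Slc22a3 (-1.47), named after their values were seen, did not pass. The list median was 0.27 (adjusted p = 0.00389; adjusted p = 0.295 with an estimated correlation). Without scramble liver 1 the pericentral median was 0.50 (adjusted p = 0.000597). Of 19 periportal genes 1 rose, 1 fell and 17 did not pass (2 and 4 adjusted over the list alone; median -0.40, adjusted p = 0.0820). The riser was Cdh1 and the faller, named after its value was seen, the lipoprotein gene Apoa4 (-1.86). Acute phase genes fell as a list. Of 28 genes, Serpina3m (-0.97, SE 0.18), Crp (-0.62, SE 0.12) and Orm3 (-1.78, SE 0.36) fell, Steap4, a metalloreductase gene, rose by 0.71 (SE 0.13), and 24 did not pass (1 rose and 4 fell adjusted over the list alone). Their median log2 fold change was -0.27 (adjusted p = 0.00389; adjusted p = 0.295 with an estimated correlation). Cyp1a2, Lgr5, Serpina3m, Crp and Orm3 had fractional counts in all 6 libraries and are uncertain.

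**Figure D3:**
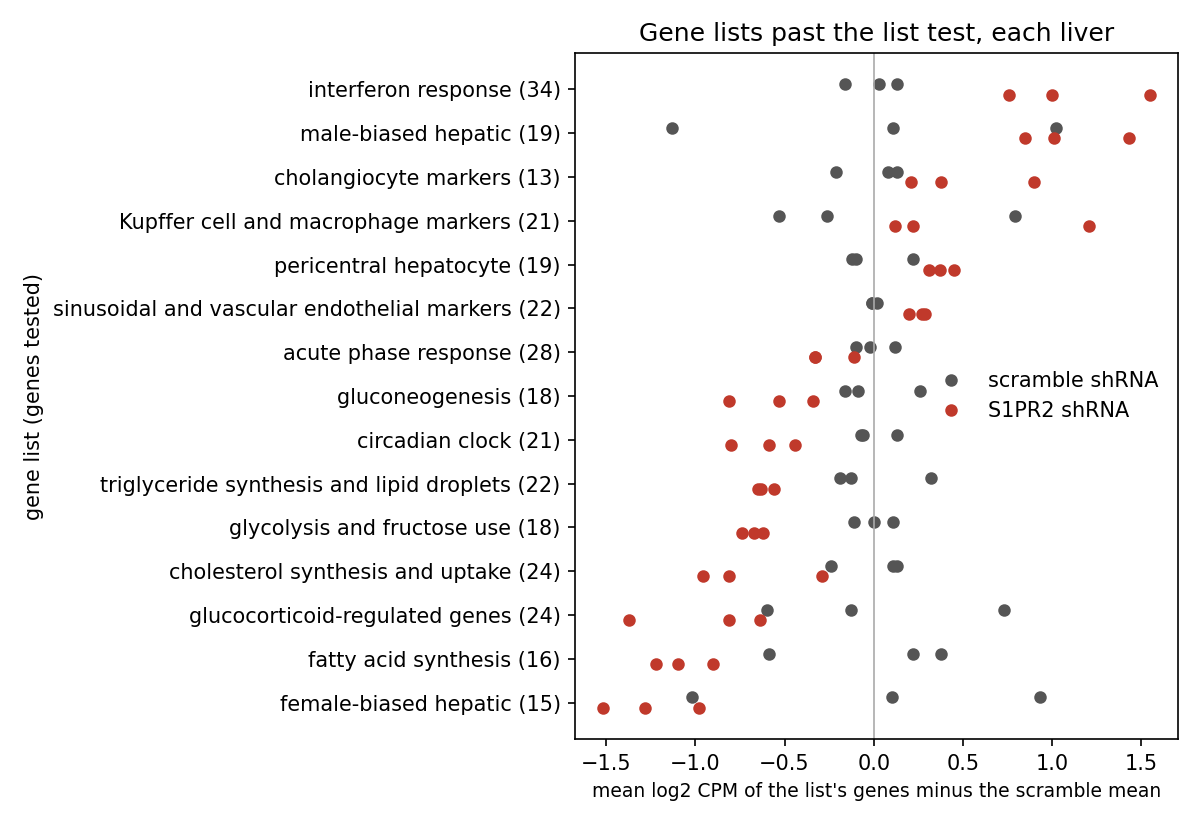
Mean log2 CPM of the tested genes of each of the 15 lists past the list test, relative to the mean of the scramble livers, with 1 point per liver (grey for scramble, red for S1pr2 shRNA) and the number of genes in parentheses. The interferon list lay at 0.76 to 1.55 in the knockdown and at -0.16 to 0.13 in the scramble livers, while the groups overlapped in the macrophage, male-biased and female-biased lists.

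Stress, signalling and growth lists did not pass, and their called members, named after their values were seen, were few. Of 24 genes of the unfolded protein and integrated stress responses 4 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.14, adjusted p = 0.111). They were the endoplasmic reticulum chaperone or cofactor genes Sdf2l1 (1.72), Creld2 (0.93) and Manf (0.80), the transcription factor gene Ddit3 (1.14), and Sel1l (-0.66). Of 29 xenobiotic genes 4 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.11, adjusted p = 0.613). Cyp1a2, Gclc (1.15), Gsta2 (1.14) and Gstp1 (0.91) rose, the last 3 being glutathione genes, and Cyp2b10 fell. Of 18 insulin signalling genes Igfbp2 rose and the genes of the regulatory PI3-kinase subunit Pik3r1 (-1.17) and the phosphatase Ptpn1 (-0.67) fell (1 and 4 adjusted over the list alone; median -0.14, adjusted p = 0.361). Other lists had a single called gene each, also when adjusted over the list alone. Of 22 ceramide genes Asah2 fell by 0.58 (median -0.06, adjusted p = 0.477), and of 14 heat shock genes Hspd1 fell by 1.08 (median -0.02, adjusted p = 0.613). Of 15 p53 targets Plk2 rose by 1.26 (median 0.19, adjusted p = 0.620), and of 23 RhoA, YAP and SRF targets Rock1 fell by 0.71 (median 0.06, adjusted p = 0.666). Of 19 cell cycle genes Rrm2 fell by 1.72, while the median was 0.03, the mean 0.04 and the direction of the test lower (adjusted p = 0.703). Of 18 immediate early genes Dusp1 fell (median -0.07, adjusted p = 0.747).

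The 7-mers TGGAGAA or GGAGAAA were present in the annotated 3' UTR of 17 of the 39 named genes that fell. Among these were S1pr2, Mttp, Acaca, Acacb, Dhcr7, Hsd17b7, Dgat2, Cd36, Hlf, Tef, Gstt3, Plcl1, Cyp2b10, Cyp2b13 and Cyp2b9. They were also present in 5 of the 33 named risers with an annotated 3' UTR long enough to scan (Cib3 and Fitm1 had none), among them Acsm2, Fcgr2b, Rnf43 and Steap4, and in Fbp1 and Stard4, which did not pass. Among the named genes that fell, G6pc, Gpi1, Me1 and Sult1e1 held neither 7-mer in the 3' UTR but had at least 1 in the coding sequence, and Slc37a4, Khk, Tkfc, Thrsp and Dusp1 held neither in either part. Each of the 15 list calls was lost with an estimated correlation, and 5 of the 15 held with the directional fry test. Those were the glycolysis and fructose, interferon, acute phase, pericentral and endothelial lists. The fatty acid (fry adjusted p = 0.069), triglyceride (0.0753), gluconeogenesis (0.123) and cholesterol (0.123) lists were among those that did not pass fry. Of the female-biased list, the 5 genes with neither 7-mer in the 3' UTR or coding sequence had a median log2 fold change of 0.06 (bootstrap interval -3.55 to 0.97) and the other 10 of -1.99.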

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

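The genes without a 7-mer site were an alternative chosen after the result was seen; all others were set beforehand. The number of changed genes (937) stayed within 1.5 times of itself under the other scalings, filters, voom, non-robust dispersion, the replicate block, FPKM and a minimum fold change of 1.5, where it ran from 723 to 982. It was 1413 with DESeq2, for which the cause was not tested, and 398 among the 8710 genes with no TGGAGAA or GGAGAAA in the 3' UTR, where fewer genes were tested and 45.2% of the calls were lower. With each liver left out in turn it lay between 231 (knockdown liver 2) and 643 (knockdown liver 1), with fewer samples in each fit. The log2 fold change of S1pr2 (-1.12) was negative under every alternative and lost its call with the replicate block (-1.115), on FPKM with a pseudocount of 0.1 (-0.901) or 1 (-0.543), and in 4 of the 6 fits that left out a liver, which ran from -1.292 to -0.949. A larger pseudocount draws the values of a gene at low FPKM together; the cause of the other losses was not tested. Of 35 lists, 15 passed with the preset correlation of 0.01, 0 with an estimated one and 5 with fry. The estimates for the 15 lists ran from -0.003 (acute phase, pericentral) to 0.74 (male-biased), with 0.469 for fatty acid and 0.486 for cholesterol genes. Where they lie far above 0.01, the preset p-values take genes as more independent than the data show. The acute phase and pericentral calls were lost too, so a larger correlation is not the whole account, and the rest was not tested. Under the other scalings, filters, tests and left-out livers the number of lists that passed lay between 14 and 19. Of the 92 other named genes, direction and side of the threshold held in 1226 comparisons, the call was lost in 221 and gained in 24; for 18 lists, with the preset correlation only, it held in 261 and was lost in 9; none was reversed. DESeq2 gave no adjusted p for 3829 genes, and the robust option does not enter camera, so no list value was made for it. Depth limits what can be said of rare cells: 2 of the 25 T, B and NK cell markers passed the count filter.

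The replicate numbers were used as a block in 1 alternative only, which called 808 genes, 662 of them among the 937, 57.7% lower. Residuals of livers with the same number correlated at -0.06, 0.22 and -0.12, and scramble liver 3 correlated best with knockdown liver 1 (0.30). These values gave no sign of pairing by number, but 3 livers per group are too few to exclude it.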

Other observations

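In this part, several tests were chosen only after the result was seen. They were those of Gene Ontology terms, of same-base 7-mers, of sites by class and by UTR length, and of site-free list members. So were those of the interferon list mean over livers with the macrophage covariate and of the difference between the interferon and macrophage medians. Some ribosomal protein genes rose in the knockdown livers. Of 115 tested genes annotated as structural constituents of the ribosome, 23 rose, 0 fell and 92 did not pass, against 3.5 rises expected (Fisher's exact test over 4622 term tests, adjusted p = 1.57e-09), with the called genes between 0.57 and 0.97 log2 units, among them Rps19 (0.97), Rpl37 (0.88), Rpl13 (0.87) and Rps10 (0.78). The median of the term was 0.12, with 82 values above 0. Many ribosomal protein genes have processed pseudogenes that can share reads, so these values are uncertain. Fisher's exact test takes genes as independent of each other. The adjusted p of this and the following terms thus do not measure the spread between livers.

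Some genes of tight junctions, the seals between neighbouring epithelial cells, rose. Of 18 tested genes of bicellular tight junction assembly 6 rose, 0 fell and 12 did not pass (0.5 rises expected, adjusted p = 0.00372), with a term median of 0.13 and 9 values above 0; the 6 were the claudins Cldn1 (1.61) and Cldn3 (1.34), occludin Ocln (1.49), Marveld2 (1.52), Marveld3 (1.47) and Cdh1 (2.68). Of 13 cholangiocyte markers, also epithelial, 4 rose (list median 0.50; the list call was lost without scramble liver 1, at 0.43), among them Krt18 (1.40), while Epcam (1.22), Sox9 (0.21), Krt7 (-0.10) and Krt19 (-0.97) did not pass. The apical plasma membrane term held 16 rises and 4 falls among 172 genes (adjusted p = 0.0155). Of 30 genes of the response to interferon-beta 8 rose and 0 fell (adjusted p = 0.000846), including Irf1 (0.82), Irgm2 (1.52) and Gbp6 (1.30). Of 52 cholesterol homeostasis genes 10 fell and 4 rose (adjusted p = 0.0291), among the falls Mttp, Apoa4 (-1.86), Nus1 (-1.22) and Abca1 (-0.90), and of 32 genes of the response to calcium ion 8 fell and 0 rose (adjusted p = 0.0218), including Txnip (-1.23) and Adam9 (-0.83).

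The fall of many transcripts went with a short sequence in their 3' UTR: of the 16384 7-mers, GGAGAAA had the most negative z, -15.84, followed by TGGAGAA at -14.17, beyond the Bonferroni bound of 4.67, and 315 of 561 fallen genes (56.1%) held one of them against 16.2% of 351 risen genes and 26.3% of uncalled ones. Of genes holding the 8-mer TGGAGAAA 13.6% fell, against 2.5% of genes without the core, and S1pr2 itself holds 2 copies. The scan picked these 7-mers on the same genes, so these shares describe its result and are no separate support. Base composition of the 3' UTR is argued against as the source of the signal at GGAGAAA. The 33 other 7-mers of its bases without the core reached -3.33 at most, and its reverse complement stood at -0.92. For TGGAGAA the same-base 7-mers and the reverse complement were not tested. Length of the 3' UTR is argued against for sites of either 7-mer. Such sites went with falls in every UTR-length class of equal size (7.7 to 16.1% with a site, 2.4 to 3.4% without). Of 12 7-mers beyond the bound on the lower side 10 held 5 bases of the core, but TATTTAT, made of A and T alone, was among the others (z -5.47, 3612 genes), and what lay behind it was not tested. A candidate explanation is seed-type silencing of other transcripts by the S1PR2 shRNA, in which case part of the changes would not pass through the receptor; the hairpin sequence is not given in the sources used here, and a change in an endogenous microRNA was not tested.

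The lower sugar and lipid lists could come from such sites in their own members, or from the control livers. Members of these 5 lists with neither 7-mer in the 3' UTR or coding sequence still had a median log2 fold change of -0.476 (95% bootstrap interval over genes -0.716 to -0.387, 43 genes), against 0.065 for all genes without a site. Over genes, this argues against sites in the members as the whole source for the 5 lists as a set. The bootstrap takes genes as independent and does not measure the spread between livers, for which site-free members were not tested. Taken alone, 4 of the lists also had intervals over genes below 0. Their medians without a site were -0.774 in fatty acid (6 genes), -0.528 in cholesterol (11), -0.557 in glycolysis (9) and -0.395 in triglyceride genes (12). Members with a site had medians of -1.454, -0.834, -0.409 and -0.744 in the same order. Of the site-free cholesterol and triglyceride genes 0 fell past the test, so sites as a part of the source stay open. For gluconeogenesis such sites stay open (median -0.126, -0.883 to 0.419, in 5 genes without a site, against -0.504 with one), and for all 5 lists, untested, silencing of a regulator, signalling through S1pr2, the collection time of day, to which the clock genes would respond, and the amount of dexamethasone drunk. Without scramble liver 1, 5 of the 5 lists passed in the lower direction; it was the highest control in the gluconeogenesis, glycolysis and triglyceride lists, where this argues against it as the sole source, and the lowest in the fatty acid and cholesterol lists, where it could not have raised the control level. The real split of the livers called 937 genes and the highest of the other splits 0 in edgeR (1 of 10 splits gave as many; 147 to 775 genes at an unadjusted p under 0.05 in the others against 2992), but 10 splits are too few for a share under 0.05.

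The higher interferon list may reflect more macrophages in the knockdown livers, since the macrophage markers rose as a list, at 1.21, 0.12 and 0.22 in knockdown and -0.53, -0.26 and 0.79 in scramble livers 1 to 3, against 1.55, 1.00 and 0.76 and -0.16, 0.13 and 0.03 for the interferon list; the difference between the lists per liver overlapped between groups (0.33, 0.87 and 0.54 against 0.37, 0.39 and -0.76). With the macrophage mean as a covariate the interferon median was 0.755 (95% bootstrap interval over genes 0.613 to 1.286), against 1.01 without the covariate. Of 34 values 33 stayed above 0. The list test (adjusted p = 2.05e-11) used the preset correlation. Without the covariate the interferon call was lost with an estimated correlation (list test adjusted p = 0.362). The macrophage median of 0.071 was low by construction, since the covariate was the mean of these same markers. Neither the list test nor this median bears on macrophage number. The group difference of the interferon list mean was 0.942 (95% interval over livers 0.187 to 1.697), which argues against macrophage number as the whole source. This leans on single livers: the difference was 0.530 (-0.426 to 1.486) without scramble liver 3. The interval also reached 0 without scramble liver 1 (0.943, -0.352 to 2.238), scramble liver 2 (1.028, -0.042 to 2.097) or knockdown liver 2 (0.929, -0.568 to 2.425). It stayed above 0 without knockdown liver 1 (0.869, 0.139 to 1.599) or knockdown liver 3 (1.112, 0.066 to 2.159). The interferon median exceeded the macrophage median by 0.508 (0.099 to 1.045) but by 0.119 (-0.475 to 0.484) without scramble liver 3 and 0.260 (-0.113 to 0.943) without knockdown liver 2. Macrophages as a part of the source stay open, since the covariate kept 74.6% of the median, between the bounds of under 50% and at least 80% set beforehand for either answer. Macrophage activation, sensing of the vector or hairpin RNA by liver cells and an effect of the receptor were not tested.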
